A study of Mus musculus with 8 samples.

How the data were processed

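Poly(A) RNA sequencing of white adipose tissue from male mice was analysed, with 8 libraries from 2 groups of 4. Per the labels, the tissue was epididymal fat, taken after 8 weeks on a Western diet and a 6 h fast. Per the labels' protocols, RNA was isolated with TRIzol, poly(A) RNA was captured on oligo-dT beads and fragmented, and cDNA synthesis was primed with random hexamers. The protocol names no step that marks the strand, and the strand setting of the counting is not given in the sources used here. Genes that overlap on opposite strands can therefore share reads in these values. HISAT2 2.0.5, featureCounts and the genome build mm10 are named in the submitters' processing notes. The annotation release is not given in the sources used here.

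The authors deposited 1 table of FPKM values (fragments per kilobase of gene per 1000000 mapped fragments) with 28295 genes and a column for each library. No row was at 0 in every library. Of the gene IDs, 28255 (99.9%) matched a reference symbol, and symbols were taken by ID because 267 names in the table differed from the reference, 26 of them having been turned into dates. Coordinates are those of the GENCODE M21 annotation of build mm10 (GRCm38), 1-based.

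FPKM values are not counts, so no count test was used as the main result. Low values nevertheless stepped in whole reads. The ratio of a library's steps at genes below an FPKM of 0.1 gave relative depth, and GENCODE M21 exon lengths gave the scale. Of the values between 0.5 and 200 reads, 97.9% lay within 0.02 reads of a whole number, and 99.1% of genes were recovered in every library. With M for 1000000 reads, the FPKM denominators recovered in this way were 22.9 to 25.5 M in WT and 24.2 to 29.1 M in the KO-labelled libraries. The reads in the listed genes came to 17.7 to 19.7 M and 15.2 to 18.7 M. They made up 74.1% to 78.6% of the denominator in WT and 62.6% to 66.1% in the KO-labelled libraries (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 allows). What made up the rest is not in the table analysed here. The reads given here are recovered from the FPKM values.

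The comparison was KO-labelled against WT, all 8 libraries in 1 fit with no covariate. Values were tested as log2(FPKM + 0.5) with limma 3.58.1 (R 4.3.3), limma-trend with robust empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment over the 14400 genes with a mean FPKM of at least 0.5. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Errors beside FPKM means are SDs over 4 libraries, and errors beside log2 fold changes are the moderated standard errors of limma. The labels name mice but not which library came from which animal, so each library was taken as 1 mouse. Cul3 was also tested with an exact two-sided permutation test.

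Of 38 gene lists fixed before the data were examined, the 37 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. The skeletal muscle list had 3 tested members and was not tested. Some results, among them those of 1 of the 37 lists, are not reported here. Camera with an estimated correlation and fry, which asks only whether a list's genes move on balance in 1 direction, were run beside it. Beside the count over all genes tested, the number of called members is given adjusted over the list alone. Genes were named by a rule fixed in advance. It took Cul3, the 10 largest rises and the 10 largest falls, and up to 4 members per list. The largest changes were restricted to called genes with a mean FPKM of at least 1 in the higher group and no overlap between groups, leaving out predicted genes, clone names, pseudogenes and receptor segments. List members were taken by the smallest adjusted p, and from a list with no call the 2 members with the highest mean FPKM. A gene on more than 1 list counts under each.

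Alternatives fixed in advance were 2 other pseudocounts, 2 other filters, 3 other scalings, limma without trend, array weights, a replicate block, each library left out in turn, protein-coding genes only, 2 other list tests and a fold threshold. Chosen after the data were seen were voom on the recovered reads, scaling to the reads in the listed genes, a fit without the libraries WT1 and WT2, and the families of genes in the closing section. The limma fit was tested on simulated data with 200 of 14400 genes changed and noise independent between genes. Genes in the real data are correlated, so the rates of this simulation need not hold for them. In the simulation the fit recovered 72% of the 100 genes changed by 1 on the log2 scale and 37% of the 100 changed by 0.5. It gave 5.22% false calls and called 1 list that had not been shifted. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.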

Results

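Gene expression was measured in the epididymal white fat of male mice fed a Western diet, a diet rich in fat and sugar, for 8 weeks and fasted for 6 h. The WT group (4 libraries) carried Cul3 alleles flanked by loxP sites and no Cre. The KO group (4 libraries) also carried a Cre recombinase driven by the promoter of Adipoq, which is active in adipocytes. Cul3 encodes cullin 3, the scaffold of a family of ubiquitin ligases, including the KEAP1 ligase that marks the transcription factor NRF2 for degradation. The comparison asks how the fat transcriptome differs once Cul3 is deleted in adipocytes. Depth was 15.2 to 19.7 M recovered reads in listed genes per library (M, 1000000 reads). Correlations of log2 values across genes were 0.945 to 0.973 within WT, 0.949 to 0.975 within the KO group and 0.896 to 0.943 between the groups, where genes are not independent replicates.

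Cul3 itself (ENSMUSG00000004364, chromosome 1, 80264923 to 80340480) was not lower in the libraries labelled KO. Its level was 11.2 ± 1.13 FPKM in WT and 12 ± 1.29 FPKM in the KO group (SD, n = 4 each). Per library it was 11.4, 9.66, 12.4 and 11.5 FPKM in WT1 to WT4, and 10.7, 11.2, 13.2 and 13.0 FPKM in KO1 to KO4, from 1128 to 1567 recovered reads. The log2 fold change was 0.09 ± 0.10 (limma adjusted p = 0.520), and the exact two-sided permutation test gave p = 0.486. The 95% interval of the KO to WT ratio ran from 0.908 to 1.25, so a fall of at most 9.19% lay within it. Scaled to a sum of 1000000 per library, the log2 fold change was 0.37 (adjusted p = 0.0477), and scaled to the reads in listed genes it was 0.34 (adjusted p = 0.0390). Over all alternatives its adjusted p ran from 0.0390 to 0.986. A value per gene does not separate the deleted exons from the rest of the transcript. Because the targeted transcript does not check the labels, the groups are called WT and KO-labelled throughout, and every direction rests on those labels.

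In the KO-labelled fat, the lists of NRF2 targets and interferon-stimulated genes were higher on average, and those of lipid synthesis and adipocyte identity lower, by camera at the preset correlation. None of these calls held when the correlation was estimated (adjusted p = 0.563 with an estimated correlation for each). Of 14400 genes tested, 1689 were higher and 2683 lower (30.4% of those tested), and 401 and 380 of these changed by at least 1 on the log2 scale. When 1 library was left out, 1100 to 1938 genes were higher and 1862 to 2794 lower. Without both WT1 and WT2, 729 were higher and 1029 lower. The split depended on scaling. Scaled to a sum of 1000000, 4226 genes were higher and 1190 lower, and scaled to the reads in listed genes, 4213 and 1265, as the median log2 fold change of all genes moved from -0.02 to 0.24 and 0.19. Beside this, listed genes held a mean of 64.5% ± 1.46 of the FPKM denominator in the KO-labelled libraries and 76.7% ± 1.92 in WT (SD, n = 4). No named gene changed sign under any of the 4 scalings tried. Of 135 named genes with a call, 17 lost it scaled to a sum of 1000000, 14 scaled to the reads in listed genes, 11 with quantile normalization and 0 with median-of-ratios scaling. Named genes were picked largely by fold change or adjusted p and do not stand for all genes. Of the 2683 lower calls, 1177 were kept scaled to a sum of 1000000 and 1264 scaled to the reads in listed genes. All 1689 higher calls were kept under both.

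On the log2(FPKM + 0.5) scale, the largest rise among the named genes was that of Prg4 (ENSMUSG00000006014, chromosome 1, 150449412 to 150466165), which encodes lubricin. Prg4 went from 1.55 ± 0.496 FPKM in WT to 32.1 ± 10.1 FPKM (log2 fold change 3.98 ± 0.24, adjusted p = 3.43e-05). As a ratio of mean FPKM, Slc22a12 (136) and Angpt4 (42.9) rose more than Prg4 (20.7). Hsd11b1 (chromosome 1, 193221634 to 193264075), whose product regenerates active glucocorticoid, rose from 7.26 ± 2.16 to 91.9 ± 4.40 FPKM (3.61 ± 0.17). Gpx3 (chromosome 11, 54902453 to 54910377), an extracellular glutathione peroxidase, rose from 86.1 ± 9.47 to 705 ± 75.5 FPKM (3.03 ± 0.12). Cbr3, a carbonyl reductase, rose by 3.54 ± 0.24 on the log2 scale. The matricellular genes Ccn5 and Thbs2 rose by 3.57 and 3.49, the angiopoietin gene Angpt4 by 3.50, and the monocyte chemokine gene Ccl12 by 3.07. Ces1f, a carboxylesterase, rose by 3.12, a value that reads shared with its close paralogs could affect. Slc22a12, a urate transporter gene known from kidney, rose from 0.0322 to 4.38 FPKM, with as few as 1 read in a WT library. The adjusted p of these 10 genes was at most 0.000242.

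**Figure D1:**
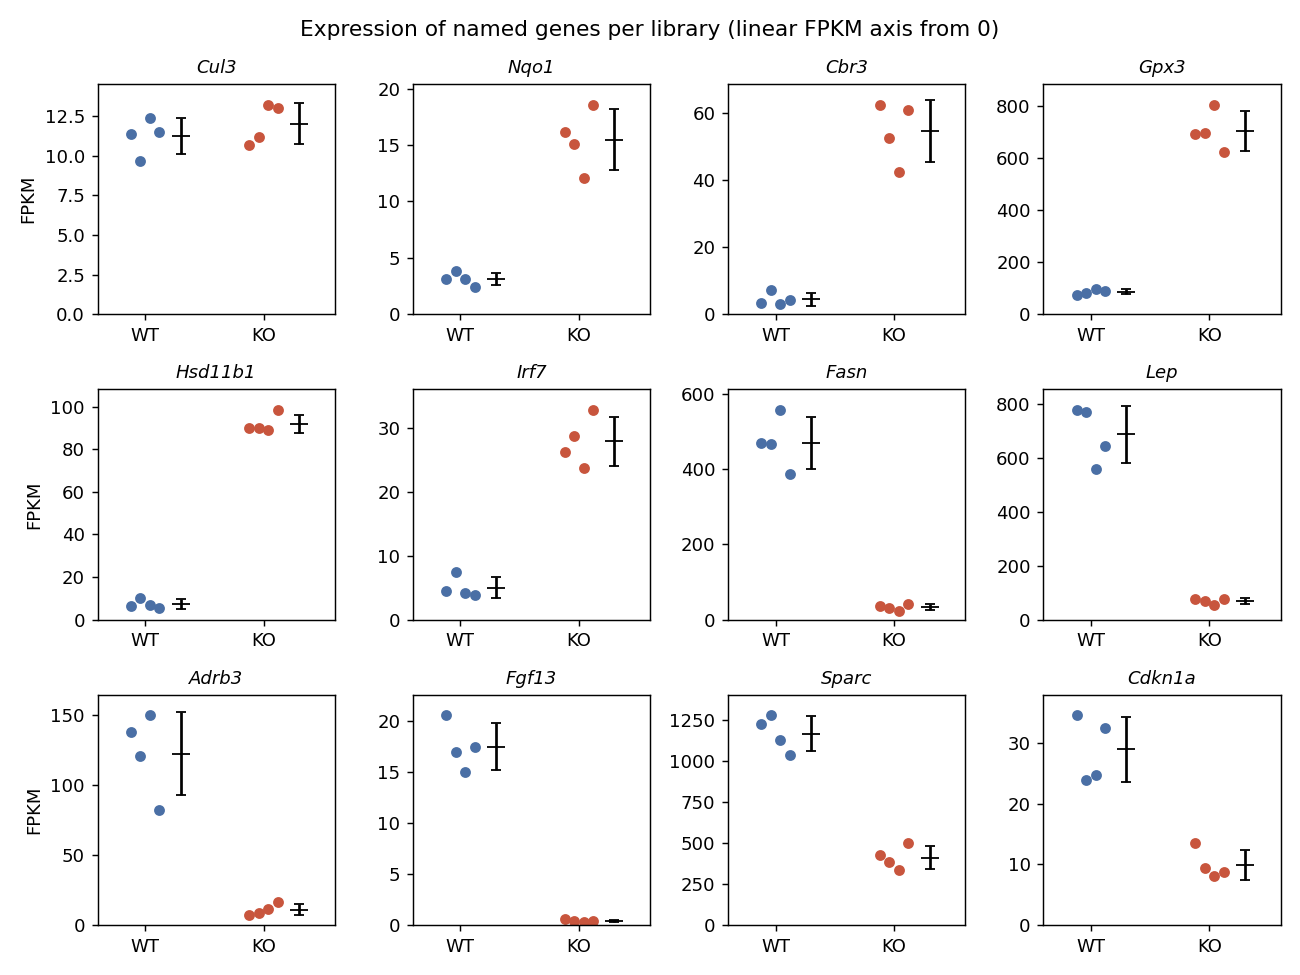
FPKM per library (points, linear axis from 0) of 12 named genes in the WT and KO-labelled groups, 4 libraries each, with the group mean and SD (bar) at the right of the points. Cul3 overlapped between the groups (11.2 against 12 FPKM), while Gpx3 was higher (86.1 against 705 FPKM) and Fasn lower (470.5 against 33.0 FPKM) in the KO-labelled libraries.

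On the log2(FPKM + 0.5) scale, the largest fall among the named genes was that of Fgf13 (ENSMUSG00000031137, chromosome X, 59062145 to 59568071), an intracellular member of the FGF family. Fgf13 went from 17.5 ± 2.31 to 0.378 ± 0.115 FPKM (log2 fold change -4.36 ± 0.12, adjusted p = 1.33e-06). As a ratio of mean FPKM, WT over KO-labelled, Rnase2a (85.5) fell more than Fgf13 (46.2). Fasn (chromosome 11, 120805846 to 120824547), the fatty acid synthase, fell from 470.5 ± 69.1 to 33.0 ± 8.13 FPKM (-3.84 ± 0.19). Lep (chromosome 6, 29060220 to 29073877), the gene of the adipocyte hormone leptin, fell from 688 ± 106 to 67.8 ± 11.1 FPKM (-3.34 ± 0.16). Adrb3, the β3-adrenergic receptor, fell by 3.46 on the log2 scale, and Pnpla3, a lipid droplet acyltransferase and lipase, by 3.43. Tmem45b fell by 3.59, Paqr9 by 3.56 and Rnase2a, of a family of near-identical ribonucleases, by 3.81, with 0 reads in at least 1 library. The adjusted p of these 8 genes was at most 0.000115. Apoa2 and Fabp1, both abundant in liver, were also lower (-3.51 ± 0.99 and -3.30 ± 0.99, adjusted p = 0.0278 and 0.0362), but their WT means came largely from WT2 (186 and 69.9 FPKM) and WT1 (34.8 and 11.2 FPKM). Without these libraries neither passed the test (-1.84 and -1.61, adjusted p = 0.0847 and 0.0952), and each call was also lost without WT1, KO3 or KO4 alone, and by voom on the recovered reads (adjusted p = 0.186 and 0.200). Fabp1 was also lost without KO2 (adjusted p = 0.0877).

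NRF2 target genes were higher as a list. Of 30 tested members, 13 rose and 3 fell (14 and 4 adjusted over the list alone), with a mean log2 fold change of 0.54 (camera adjusted p = 0.000115, and adjusted p = 0.563 with an estimated correlation). The mean was 0.83 scaled to a sum of 1000000 and 0.78 scaled to the reads in listed genes, still with a call. Besides Cbr3, the quinone reductase gene Nqo1 rose from 3.13 ± 0.564 to 15.5 ± 2.68 FPKM (2.14 ± 0.15), Gclm, the modifier subunit of glutamate-cysteine ligase, by 1.31 ± 0.09 and glutathione reductase (Gsr) by 1.06 ± 0.08. In the list of cysteine, taurine and glutathione metabolism, 8 of 20 members rose and 4 fell (8 and 4 adjusted over the list alone), among the former Gclc, the catalytic subunit of the same ligase (1.34 ± 0.13), but the list did not pass (camera adjusted p = 0.0819). It passed by fry (adjusted p = 0.00318), with quantile normalization (0.0313), with a mean FPKM of at least 1 (0.0249), without WT2 (0.0388), without KO2 (0.0469) and without WT1 and WT2 (0.0122).

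Proteasome subunit genes were lower. Of 31 proteasome subunits, 27 fell and none rose (29 and 0 adjusted over the list alone), with a mean log2 fold change of -0.43 (camera adjusted p = 1.83e-09, and adjusted p = 0.563 with an estimated correlation). Examples were Psmb7, from 15.7 ± 2.72 to 8.66 ± 0.367 FPKM (-0.81 ± 0.12), and Psmc4 (-0.63 ± 0.08). The mean was -0.16 scaled to a sum of 1000000 and -0.18 scaled to the reads in listed genes, still with a call. Camera tests a list against all other genes, so a scaling that shifts all genes can leave the call in place. Here and for the other lists, a call kept under these scalings shows a position relative to other genes, not a fall or rise of fixed size. In the cullin-RING ligase list, 16 of 35 members fell and 3 rose (16 and 3 adjusted over the list alone). Nedd8, the ubiquitin-like activator of cullins, fell by 0.82 on the log2 scale, and Dcun1d3, of the neddylation machinery, rose by 0.79. The list's mean was -0.17 (camera adjusted p = 0.0166, and adjusted p = 0.563 with an estimated correlation), but it was 0.10 when scaled to a sum of 1000000 and 0.06 when scaled to the reads in listed genes, without a call. Without KO1 its adjusted p was 0.0694, and with quantile normalization 0.0729. Of 20 p53 target genes, 13 fell and 3 rose (13 and 3 adjusted over the list alone; mean -0.40, camera adjusted p = 0.00642, and adjusted p = 0.563 with an estimated correlation). They included the cell-cycle inhibitor gene Cdkn1a, from 29.0 ± 5.38 to 9.94 ± 2.47 FPKM (-1.51 ± 0.18), and Ccng1 (-1.37 ± 0.12), and under the same 2 scalings the mean was -0.14 and -0.17, still with a call.

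Lipid synthesis genes were lower on average. In the fatty acid and triglyceride synthesis list, 16 of 20 members fell and none rose (16 and 0 adjusted over the list alone; mean -1.55, camera adjusted p = 1.83e-09). Elovl6, a fatty acid elongase, fell from 10.7 ± 1.33 to 1.58 ± 0.148 FPKM (-2.43 ± 0.10). Acss2 and Acly, which supply acetyl-CoA, fell by 2.91 and 1.66 on the log2 scale. In cholesterol synthesis, 19 of 23 fell and none rose (20 and 0 adjusted over the list alone; mean -1.11, camera adjusted p = 1.65e-10), among them Nsdhl (-2.19 ± 0.14). Neither call held when the correlation was estimated (adjusted p = 0.563 with an estimated correlation for both).

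Adipocyte identity genes were lower, with 18 of 23 members down and none up (18 and 0 adjusted over the list alone; mean -0.96, camera adjusted p = 6.02e-07). Besides Lep and Adrb3, the lipid droplet gene Cidec fell from 1445 ± 188 to 409.8 ± 60.5 FPKM (-1.82 ± 0.15) and the adipogenic factor gene Cebpa from 265 ± 30.2 to 133 ± 6.42 FPKM (-0.99 ± 0.11). In lipolysis, 14 of 19 fell and 2 rose (15 and 3 adjusted over the list alone; mean -0.63, camera adjusted p = 0.000794), with Mgll, a monoglyceride lipase, down by 1.42 ± 0.15 on the log2 scale and the droplet protein gene Plin5 up by 1.90 ± 0.27. The lipolysis mean was -0.36 scaled to a sum of 1000000 and -0.39 scaled to the reads in listed genes, still with a call. In the thermogenic list, 5 of 13 fell and 1 rose (5 and 1 adjusted over the list alone, mean -0.63, camera adjusted p = 0.0346). Pm20d1 (-1.27 ± 0.11) and Otop1 (-1.60 ± 0.19) had the smallest adjusted p, and Cox8b fell further (-2.19 ± 0.32). Each of these 3 lists lost its call when the correlation was estimated (adjusted p = 0.563 with an estimated correlation), and the thermogenic list also without KO1 (adjusted p = 0.0694) and without WT1 and WT2 (adjusted p = 0.0645). KO4 had the highest adipocyte identity mean of its group (7.23 against 6.75 to 6.77 log2 units), and WT4 the lowest of its own (7.48 against 7.84 to 8.07).

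Oxidative phosphorylation genes were lower on average. Of 60 oxidative phosphorylation genes, 31 fell and none rose (39 and 0 adjusted over the list alone; mean -0.49, camera adjusted p = 4.23e-09, and adjusted p = 0.563 with an estimated correlation). They included Cox5a, from 18.1 ± 1.94 to 10.6 ± 1.10 FPKM (-0.74 ± 0.10), and Atp5f1 (-0.62 ± 0.09). The mean was -0.23 scaled to a sum of 1000000 and -0.24 scaled to the reads in listed genes, still with a call. Reads of the mitochondrial chromosome made up 1.66% ± 0.447 of the denominator in the KO-labelled libraries and 3.06% ± 0.449 in WT (SD, n = 4; exact two-sided permutation test, p = 0.0286). In branched-chain amino acid catabolism, 8 of 19 fell and none rose (9 and 0 adjusted over the list alone; mean -0.37, camera adjusted p = 0.00412, and adjusted p = 0.669 with an estimated correlation), among them Pcca (-0.86 ± 0.14). Its mean was -0.11 and -0.12 under those scalings, and it did not pass with quantile normalization (adjusted p = 0.0566) or by fry (adjusted p = 0.0617). Fatty acid oxidation did not pass (camera adjusted p = 0.275), with 6 of 23 down and 3 up (7 and 4 adjusted over the list alone). Its mitochondrial entry enzyme gene Cpt1a rose (0.47 ± 0.09), a call lost without WT1 and WT2 (adjusted p = 0.0782). The list passed without a filter (adjusted p = 0.0479) and without KO4 (adjusted p = 0.0336).

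Interferon-stimulated genes were higher, with 14 of 19 up and none down (14 and 1 adjusted over the list alone; mean 1.26, camera adjusted p = 1.83e-09, and adjusted p = 0.563 with an estimated correlation). The transcription factor gene Irf7 rose from 4.97 ± 1.66 to 27.9 ± 3.86 FPKM (2.41 ± 0.19), and Oasl2 from 4.15 ± 0.955 to 17.9 ± 2.18 FPKM (2.0 ± 0.15). Of 16 inflammatory cytokine genes, 7 rose and none fell (8 and 1 adjusted over the list alone; mean 0.66, camera adjusted p = 0.00183, and adjusted p = 0.563 with an estimated correlation). Lcn2, an acute-phase protein gene, rose from 2.74 ± 0.637 to 15.2 ± 1.87 FPKM (2.29 ± 0.14), and the chemokine gene Ccl7 by 1.08 ± 0.14. This list missed the threshold when scaled to a sum of 1000000 (adjusted p = 0.0529), although its mean was then larger (1.02). Of 18 macrophage markers, 8 rose and none fell (9 and 0 adjusted over the list alone; mean 1.0, camera adjusted p = 1.21e-05, and adjusted p = 0.563 with an estimated correlation), including the Fc receptor gene Fcgr1 (2.17 ± 0.28) and Aif1 (1.54 ± 0.21), but by fry the list did not pass (adjusted p = 0.0598). The mean of the macrophage markers was 3.90 to 4.01 log2 units in WT1 to WT3 but 5.13 in WT4, above the 4.59 of KO4 and below the 5.24 to 5.59 of KO1 to KO3. MHC class II genes passed narrowly (mean 0.61, camera adjusted p = 0.0346, and adjusted p = 0.604 with an estimated correlation), with 1 of 8 members called (1 adjusted over the list alone). That member, H2-Aa, rose by 1.08 ± 0.29, a call lost without any of WT1, WT2, WT3, KO1, KO2 or KO3 (adjusted p = 0.0538 to 0.0677), and the list lost its call without WT2, WT3, KO1 or KO2 (adjusted p = 0.0572 to 0.0867). It also lost it without WT1 and WT2 (0.0900), scaled to a sum of 1000000 (mean 0.91, 0.181), scaled to the reads in listed genes (mean 0.85, 0.190) and by fry (0.128).

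**Figure D2:**
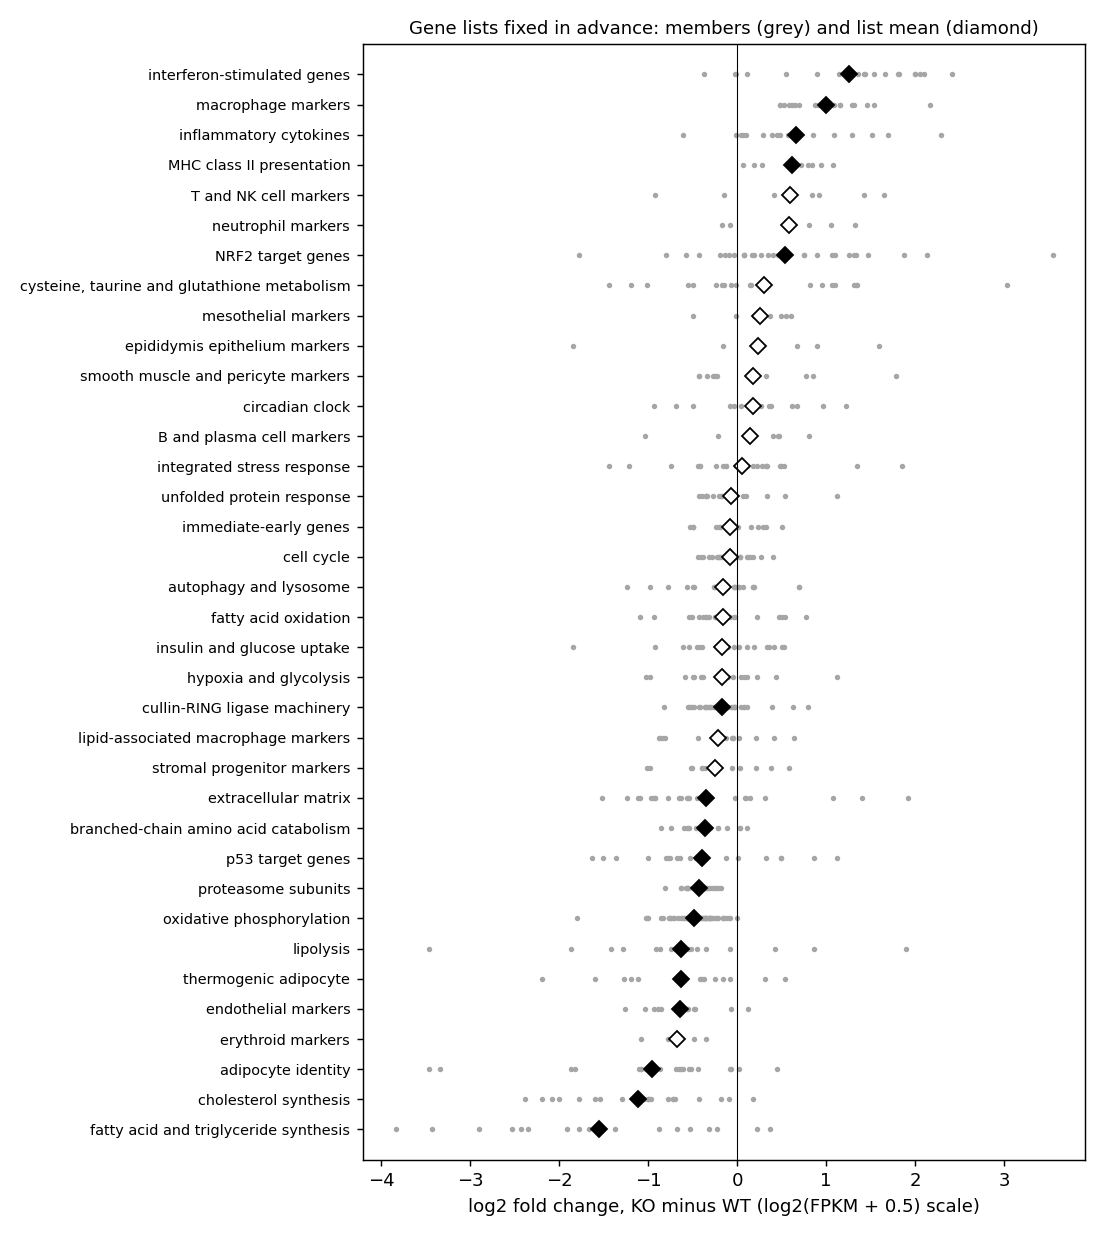
Log2 fold change (KO-labelled minus WT, log2(FPKM + 0.5) scale) of the members of 36 gene lists (grey points) and the list mean (diamond, filled where camera at the preset correlation gave an adjusted p under 0.05, open otherwise). Fatty acid and triglyceride synthesis had the lowest mean (-1.55) and interferon-stimulated genes the highest (1.26).

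Endothelial markers moved the other way from macrophage markers. Of 15 endothelial genes, 13 fell and none rose (13 and 0 adjusted over the list alone; mean -0.64, camera adjusted p = 8.77e-06, and adjusted p = 0.563 with an estimated correlation), among them Robo4 (-0.85 ± 0.11) and Egfl7 (-1.26 ± 0.19). Their mean was -0.38 scaled to a sum of 1000000 and -0.39 scaled to the reads in listed genes, still with a call. In the extracellular matrix list, 13 of 24 fell and 3 rose (13 and 3 adjusted over the list alone; mean -0.35, camera adjusted p = 0.0299, and adjusted p = 0.762 with an estimated correlation). Sparc fell from 1166 ± 108 to 410.2 ± 68.0 FPKM (-1.52 ± 0.14), Col6a1 fell by 1.11 ± 0.13 on the log2 scale and Thbs1 rose by 1.92 ± 0.16. The matrix list lost its call without WT4 (adjusted p = 0.102) and without KO4 (adjusted p = 0.104), and WT4 had its highest mean (6.09 against 5.46 to 5.56 log2 units in the other WT libraries). It also lost its call with quantile normalization (adjusted p = 0.102), array weights (0.0921) and fry (0.0869), and kept it with means of -0.07 and -0.10 under the 2 scalings above. Of 10 smooth muscle and pericyte markers, 3 rose and none fell (3 and 2 adjusted over the list alone), with Des (0.86 ± 0.09) and Cnn1 (1.79 ± 0.20) among the rises. The list's mean of 0.18 and median of -0.24 differed in sign (camera adjusted p = 0.595). Of 12 stromal progenitor markers, 4 fell and 1 rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.357), with Cd55 at -1.01 ± 0.12 and Ly6a at 0.58 ± 0.08. The progenitor list passed without a filter (adjusted p = 0.0298) and without WT1 and WT2 (adjusted p = 0.0357).

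**Figure D3:**
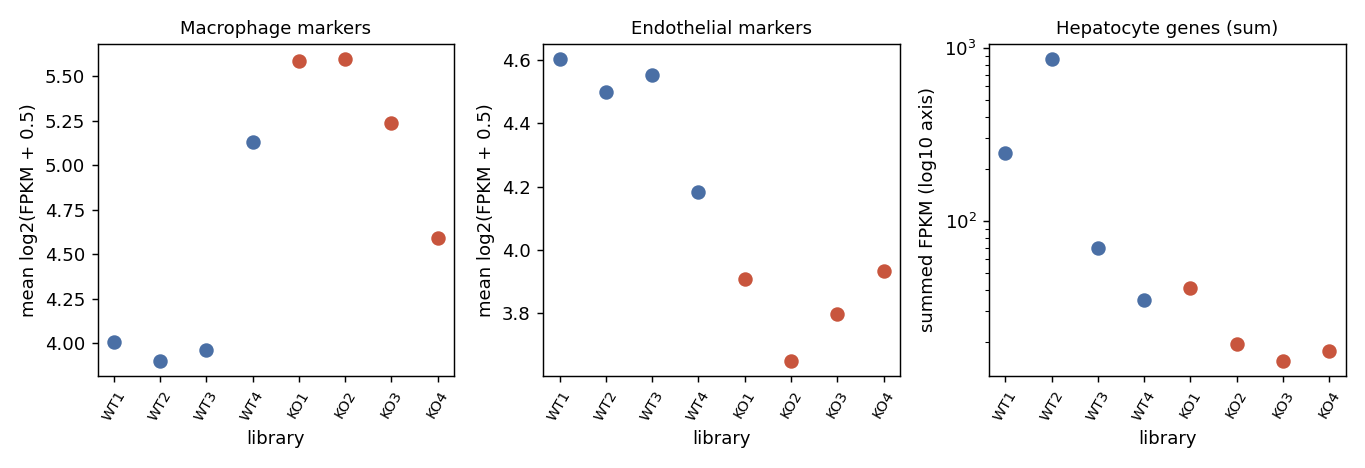
Per library, the mean log2(FPKM + 0.5) of the macrophage and endothelial markers and the summed FPKM of hepatocyte genes (log10 axis), WT in blue and KO-labelled in red. WT4 stood above the other WT libraries in macrophage markers (5.13 log2 units), and hepatocyte genes summed to 861 FPKM in WT2 and 246 FPKM in WT1 but to 15.6 to 69.9 FPKM elsewhere.

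Further lists that did not pass camera with all libraries are described here, and their called members are given with the adjusted p of the list. The insulin and glucose uptake list (5 of 18 up and 4 down, 5 and 6 adjusted over the list alone, adjusted p = 0.771) held the insulin receptor gene Insr (0.42 ± 0.09; adjusted p = 0.0745 without WT1 and WT2) and the receptor's inhibitor gene Grb14 (-1.84 ± 0.21). In hypoxia and glycolysis (2 of 17 up and 5 down, 2 and 6 adjusted over the list alone, adjusted p = 0.357), Ndrg1 rose (1.12 ± 0.09) and Ldha fell (-0.98 ± 0.12). The integrated stress response (2 of 24 up and 5 down, 2 and 5 adjusted over the list alone, adjusted p = 0.704) held Slc7a5 (1.85 ± 0.15), an amino acid transporter gene, and Phgdh (-1.45 ± 0.17), of serine synthesis. The unfolded protein response (3 of 19 up and 4 down, 3 and 4 adjusted over the list alone, adjusted p = 0.433) held Herpud1 (0.53 ± 0.07). In autophagy and lysosome (1 of 23 up and 6 down, 1 and 6 adjusted over the list alone, adjusted p = 0.353), Ctsd, a lysosomal protease gene, fell by 0.98 on the log2 scale and Npc2 by 1.24. Of the circadian clock genes (4 of 15 up and 3 down, 4 and 3 adjusted over the list alone, adjusted p = 0.275), Hlf rose (1.23 ± 0.15) and Nr1d1 fell (-0.93 ± 0.15). T and NK cell markers (4 of 7 up and none down, 4 and 1 adjusted over the list alone, adjusted p = 0.0573) were led by Nkg7 (1.65 ± 0.27). This list passed without any 1 of WT1, WT2, WT3, WT4, KO3 or KO4 (adjusted p = 0.0119 to 0.0369), without WT1 and WT2 (0.0141), without a filter (1.51e-06), with protein-coding genes alone (0.0422) and by fry (0.0153). Neutrophil markers (2 of 5 up and none down, 2 and 0 adjusted over the list alone, adjusted p = 0.275) held Csf3r (1.05 ± 0.28) and passed without a filter (adjusted p = 0.0494), and B and plasma cell markers (1 of 6 up and 1 down, 1 and 1 adjusted over the list alone, adjusted p = 0.570) held Cd79b (0.81 ± 0.22) and Ighm (-1.04 ± 0.31). The calls of Csf3r, Cd79b and Ighm were each lost without at least 5 of the 8 libraries in turn.

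Of lipid-associated macrophage markers, 1 of 13 fell and none rose (1 and 0 adjusted over the list alone, adjusted p = 0.595), the fatty acid binding protein gene Fabp5 (-0.88 ± 0.13). WT4 had the highest mean of this list (5.87 log2 units, against 4.30 to 4.96 in the other WT libraries and 4.24 to 4.88 in the KO-labelled ones), and without WT4 the mean fold change went from -0.22 to 0.12 (adjusted p = 0.629). Of 24 cell cycle genes, 2 fell (0 adjusted over the list alone, adjusted p = 0.732), the cyclin genes Ccnd1 and Ccne1, whose calls were each lost without at least 5 of the libraries in turn. Without WT1 and WT2 the cell cycle list passed as lower (mean -0.36, adjusted p = 0.00278), with WT4 at a list mean of 1.96 log2 units against 1.42 in WT3 and 1.22 to 1.41 in the KO-labelled libraries. Without WT4 alone the mean fold change was 0.10 (adjusted p = 0.255). Of 15 immediate-early genes, 2 fell (2 adjusted over the list alone, adjusted p = 0.595), Ier2 and Btg2. Both lost their call scaled to a sum of 1000000 (adjusted p = 0.101 each) and to the reads in listed genes (0.0725 and 0.0740), and Ier2 also without WT1 and WT2 (0.0925). No member was called among 9 mesothelial genes (adjusted p = 0.353), 5 epididymis genes (adjusted p = 0.754) and 5 erythroid genes (adjusted p = 0.347), and none adjusted over the list alone. The mesothelial gene Msln passed as lower without WT1 (-0.82, limma adjusted p = 0.0425) and without WT1 and WT2 (-1.08, 0.0119). Epididymis transcripts were abundant in single libraries, with Crisp1 at up to 203 FPKM in KO1 and Lcn5 at 42.0 FPKM in WT2. Hbb-bs was 259 ± 91.1 FPKM in WT and 153 ± 67.7 FPKM in the KO-labelled libraries (adjusted p = 0.144), and passed as lower without WT4 (adjusted p = 0.0380) and with array weights (adjusted p = 0.0262). So did the erythroid gene Hba-a1 (limma adjusted p = 0.0242 and 0.0157). In the untested skeletal muscle list, Acta1 (-1.28 ± 0.29, adjusted p = 0.0123) and Myl1 (-0.55 ± 0.17, adjusted p = 0.0410) were lower, and the call of Myl1 was lost without any library but KO4.

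Counts of 0 called members were set beside limma at an unadjusted p under 0.05 and beside voom on the recovered reads. In the 14 lists with 0 called rises, 0 members rose by either measure. Of the 10 lists with 0 called falls, the MHC class II genes and the macrophage, neutrophil, mesothelial and epididymis markers had 0 by either, and the interferon-stimulated genes and T and NK cell markers 1 unadjusted and 0 by voom. The inflammatory cytokines had 1 by each, and the smooth muscle and pericyte markers 3 unadjusted and 2 by voom. The erythroid markers had 1 unadjusted and 0 by voom.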

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

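In this part the tests of an exchanged library, of other cell types, of the deleted exons, of the adipocyte share and of the adipocyte list mean without WT1 and WT2 were chosen after the values they rest on had been seen. A library was singled out where its gap to the nearest of the other 3 in its group exceeded Dixon's 95% critical value, which chance gives in about 1 of 20 groups. Of 376 groups of 4 values, 23 stood out, against 18.8 from chance. KO4 accounted for 9 and WT4 for 7 of them.

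KO4 was high in adipocyte and lipid lists. Its adipocyte identity mean was 7.23 log2 units, its fatty acid and triglyceride synthesis mean 5.45, its lipolysis mean 5.11 and its fatty acid oxidation mean 4.54. It was also high in Hsd11b1 (98.5 FPKM), Cidea (0.486 FPKM) and Pccb (29.96 FPKM), and low in the macrophage gene Aif1 (4.93 FPKM). WT4 was high in macrophage markers (5.13 log2 units), extracellular matrix genes (6.09 log2 units), Lcn2 (3.69 FPKM), Oas1a (5.18 FPKM) and Csf3r (2.40 FPKM). It was low in branched-chain amino acid catabolism (3.81 log2 units) and Chac1 (2.53 FPKM). Elsewhere, Ccl12 was low in KO1 (11.4 FPKM), Myl9 in KO2 (27.9 FPKM), Fabp5 in KO3 (21.9 FPKM) and Gzmb in WT2 (0.116 FPKM). The epididymal gene Lcn5 was high in WT2 (42.0 FPKM) and listed at 0.093 FPKM in KO2 against 0 in the other KO-labelled libraries. The FPKM denominator of KO1 was high at 29.1 M (M, 1000000 reads). Of 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many as 4372 genes. That is the smallest share that 35 splits allow, so it argues against chance without excluding it. A difference other than genotype that runs with the groups would give the same result. The highest other split, WT1, WT2 and WT3 with KO4 against the rest, called 378, and the next 3.

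Cul3 was not lower in the KO-labelled libraries, although 4372 genes differed between the groups. A single library exchanged between the groups is argued against by the NRF2 target list, whose lowest KO-labelled library lay 0.257 log2 units above the highest WT library, more than the larger within-group SD of 0.132. The size of this gap does not address an exchange of both whole groups, but its direction does. The KEAP1 ligase marks NRF2 for degradation, so loss of its scaffold would raise NRF2 targets. An exchange of the groups would make them lower in the KO-labelled libraries. They were higher there (13 of 30 up and 3 down, mean log2 fold change 0.54). This argues against such an exchange without excluding it, as the camera call was lost with an estimated correlation (adjusted p = 0.563). Cul3 mRNA of cells other than adipocytes could hide a loss, since the 95% interval of the ratio allowed a fall of 9.19%, but the adipocyte share of Cul3 mRNA is not known here. Deleted exons that leave most of the transcript in place could also give the observed ratio of 1.07, and a value per gene keeps that open.

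Hepatocyte transcripts were high in WT2 and next in WT1, with Alb at 104 and 49.96 FPKM and Apoa2 at 186 and 34.8 FPKM, against at most 9.75 FPKM for Alb and 3.32 FPKM for Apoa2 in the KO-labelled libraries. Liver RNA carried into the libraries is a candidate source, because of 40 further hepatocyte genes listed before their values were seen, 33 (82.5%) were highest in WT2 and next in WT1, against a bound of over 80% (Itih4 was highest in KO3). A lower level of these transcripts in KO-labelled fat was put to the fit without WT1 and WT2, where limma called 0 (0.0%) of the further genes lower (0 at an unadjusted p under 0.05; 0 of 21 with all libraries, 5 unadjusted, 0 by voom). With 3 of them tested there, this decides nothing, by a rule of at least 10 tested genes that was added after the values were seen. Of 40 hepatocyte genes tested, 8 were lower with all libraries, all among those first noticed. Of these 8, 2 (Ttr and Serpina1c) stayed lower without WT1 and WT2 (limma adjusted p = 0.0249 and 0.0328). WT3, which stays in that fit, had a hepatocyte sum of 69.9 FPKM. The sum was 34.8 FPKM in WT4 and 15.6 to 41.1 FPKM in the KO-labelled libraries. The 2 calls therefore cannot tell a difference between the groups from liver RNA, and both stay open.

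Adipocyte identity genes were lower in the KO-labelled libraries (18 of 23). A lower share of adipocytes alone would raise the markers of all other cell types alike. Macrophage and endothelial markers moved apart by 1.64 log2 units (standard error 0.474), but the exact two-sided permutation test did not pass (p = 0.0571). In macrophage markers WT4 (5.13 log2 units) lay above KO4 (4.59 log2 units). Both lists were picked after they had been seen to move in opposite directions, so this difference decides nothing. The endothelial mean by itself was lower by 0.637 log2 units (exact two-sided permutation test, p = 0.0286), and the macrophage mean higher by 1.0 (p = 0.0571 by the same test). The endothelial mean also stayed lower under the 2 scalings above (-0.38 and -0.39). A lower share of adipocytes alone would raise it, so this argues against that as the only change, though the list was picked after its fall was seen. A lower share beside other changes and more macrophages both stay open. Liver RNA in WT1 and WT2 as the whole cause is argued against by the mean of the adipocyte identity list. Without these libraries that mean still differed by -0.784 log2 units (standard error 0.215, camera adjusted p = 1.6e-05 at the preset correlation). This rests on WT3 and WT4 alone as the WT group (7.84 and 7.48 log2 units), so the standard error is itself uncertain. WT1 and WT2 also had the highest means of that list (7.94 and 8.07 log2 units), where added liver RNA would lower them. Without these libraries 8 of the 18 calls were kept (44.4%), below 50%, the result set in advance for liver RNA as the cause. That bound did not allow for the smaller fit, which kept 37.1% of all lower calls, so this count decides nothing. The mean log2 fold change of the 18 genes went from -1.20 (SD 0.89) to -1.04 (SD 0.88).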

How the results depend on the processing

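The voom fit, the scaling to the reads in listed genes and the fit without WT1 and WT2 were chosen after the data were seen. No gene called with all libraries was called in the other direction under any setting. Of 135 named genes with a call, 123 kept it when any 1 library was left out. Over all genes fewer calls were kept, with 1071 of 1689 higher and 1827 of 2683 lower calls kept without WT1. Genes lower numbered 1862 to 2794 and genes higher 1100 to 1938 when 1 library was left out, with 1100 without WT1 and 1104 without KO3. With fewer samples, the fit without WT1 and WT2 called 729 higher and 1029 lower. A fold threshold of 1 on the log2 scale left 401 and 380. With an estimated correlation camera called 0 lists higher and 0 lower (0 and 1 at an unadjusted p under 0.05), while fry called 5 and 10.

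Scaled to a sum of 1000000, 4226 genes were higher and 1190 lower, 3 lists were higher, and Cul3 was at 0.368. Scaled to the reads in listed genes, the values were 4213, 1265 and 0.335. The replicate numbers did not pair the samples (correlations of same-numbered libraries -0.06, -0.13, 0.17 and -0.32). With the replicate block 1113 genes were higher and 1995 lower, and it ended the call of 12 named genes and of no list. Quantile normalization gave a share of 46.7% higher among calls, against 38.6%.

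Under the scalings the mean of the called cullin-RING list changed sign (0.1 and 0.062, without a call) but its direction by camera, which is relative to all other genes, did not, and the means of 9 lists with no call changed sign under at least 1 scaling. The lists below turned in direction by camera, and the genes in sign, without a call in either setting, and the cause was not tested. Without a filter this was the integrated stress response (0.052). Scaled to 1000000 they were B and plasma cell (0.52) and epididymis markers (0.421), whose means kept their sign, and scaled to listed reads the same lists (0.332 and 0.338). With quantile normalization they were fatty acid oxidation (-0.011), insulin and glucose uptake (-0.043), the unfolded protein response (0.088) and autophagy and lysosome (0.023). Array weights turned cell cycle (0.004) and the block insulin and glucose uptake (-0.166). Without WT1 and WT2, Upk3b (-0.382) and mesothelial markers (-0.297) turned. Leaving out 1 library gave -0.008 to 0.558 for Upk3b, -0.126 to 2.602 for Crisp1, -0.222 to -0.127 for insulin and glucose uptake and -0.208 to 0.104 for cell cycle. It gave -0.407 to 0.118 for lipid-associated macrophage, -0.11 to 0.216 for B and plasma cell and -0.723 to 0.639 for epididymis markers, and -0.172 to 0.038 for immediate-early genes.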

Other observations

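The families of genes in this part were chosen after the data were seen and tested as the lists were, and none of 13 passed by camera with an estimated correlation (adjusted p = 0.318 or more, 1 at an unadjusted p under 0.05), while fry called 4 higher and 5 lower. In the KO-labelled fat, all 10 tested genes of the interferon-inducible p200 family, some members of which sense DNA, rose (mean log2 fold change 1.80, camera adjusted p = 4.05e-10). Ifi204 rose from 6.72 ± 1.91 to 24.5 ± 2.88 FPKM and Ifi213 from 0.298 ± 0.0807 to 4.80 ± 0.902 FPKM (SD, n = 4), though reads can be shared within this family. Of 7 Schlafen genes, 5 rose, led by Slfn1 (2.87 ± 0.17), and of 10 Toll-like receptor genes, 5 rose, among them Tlr7 (1.89 ± 0.33) and Tlr9 (1.81 ± 0.29), and Tlr5 fell (-0.42 ± 0.12). Immune cells are among those that express Toll-like receptors, and 8 of 18 macrophage markers rose beside them. In the mean of those markers WT4 stood apart from the other WT libraries (5.13 against 3.90 to 4.01 log2 units). Whether these rises are linked was not tested. Of 18 glutathione S-transferase genes, 9 rose and 2 fell, with Gstm1 from 300.0 ± 65.4 to 1104 ± 283 FPKM and Gstz1 at -1.14 ± 0.17.

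In 3 families of mitochondrial genes, part of the members fell. Of 13 mRNAs encoded by mitochondrial DNA, 9 fell and none rose (mean -0.89, camera adjusted p = 0.000167), led by mt-Cytb (-1.27 ± 0.21). Of 77 mitochondrial ribosomal protein genes, 34 fell and none rose (mean -0.33, camera adjusted p = 7.1e-07), and of 22 genes of the import translocases, 11 fell and none rose (mean -0.43). At an unadjusted p under 0.05, 0, 0 and 1 members of these 3 families rose by limma, and voom called 0 higher in each. Cytosolic ribosomal protein genes went the other way, with 17 of 79 up and 3 down (mean 0.20, camera adjusted p = 6.56e-05).

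The other families were complement components (6 of 16 up, 1 down, camera adjusted p = 0.00741, with the macrophage genes C1qb and C1qc among the rises), tubulins (1 of 11 up, 4 down, 0.0661), carboxylesterases (2 of 7 up, 0.291), aldo-keto reductases (2 of 10 down, 0.177) and guanylate-binding proteins (2 of 7 up, 1 down, 0.254), the numbers in brackets ending in the camera adjusted p.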
